A study of Escherichia coli str. K-12 substr. MG1655 with 15 samples.

How the data were processed

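Total RNA of Escherichia coli K-12 MG1655, extracted with Trizol from cells grown in LB medium at 37 °C to an OD600 near 4.0, was used in 5 groups of 3 libraries. Per the labels, RNA was untreated, treated with DNase, treated with DNase and deacylated, treated with DNase, oxidized and deacylated, or treated with DNase, deacylated and oxidized before 3' adapter ligation. Reverse transcription products of 35 to 200 bp were selected on a gel and tailed with poly-A. They were amplified with a primer of TGG overhang, which selects ends in CCA, and a primer with 20 T. The labels did not name the oxidant. Groups and replicate numbers came from the sample labels.

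The deposited values are counts of reads covering each of 4641652 positions on the forward and reverse strand, 1 table per library. Per the submitters' processing notes, reads were processed with cutadapt 1.11, aligned with Bowtie2 2.2.8 to build ASM584v2 and handled with SAMtools 1.4. Trimming settings, filters and the treatment of reads that fit several places were not stated, so the division of reads among identical gene copies is unknown. The libraries were made by PCR without molecular identifiers, so counting error understates the true error and no counting intervals were used. Depth on the opposite strand of a tRNA gene was at most 0.0274% of that gene's depth.

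The gene table given for build ASM584v2 held 86 tRNA genes. No genome sequence was used, so genes of identical product and anticodon were summed to 42 species, of which 21 had more than 1 gene. Anticodons, modification lists and the base that holds each modified position came from textbook knowledge of E. coli tRNA and not from the files. Abundance was the number of reads over the 3'-terminal base. The stop fraction at a base was the loss of depth from its 3' neighbour to that base, divided by the depth of the neighbour, with bases counted from the 5' end. Summed depth per library lay between 179997323 and 347987157, and tRNA 3'-end reads between 4804363 and 8899274. Reads covered 6.84% ± 2.25 of genome positions in untreated libraries and 1.22% ± 0.165 after oxidation then deacylation (SD, n = 3).

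The 5 comparisons were DNase against untreated, deacylated against DNase, each oxidized group against deacylated, and oxidized then deacylated against deacylated then oxidized. Only the 6 libraries compared entered each fit. Abundance was tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr). Stops were tested with limma 3.58.1 (trend) on the empirical logit with an offset of 0.5 at bases with a mean depth of at least 100. Benjamini-Hochberg adjusted p under 0.05 counted as a call, and all tests were two-sided. Errors are SD over libraries for shares and stop fractions and SE of the fit for log2 folds. Folds of abundance are relative to TMM scaling and so differ from ratios of the raw shares of tRNA reads. Overlap of groups was judged on the raw shares. These depend on each other, since a large rise of a species lowers the shares of others.

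Lists were tested with fry in limma, which asks whether the members of a list move on balance in 1 direction and does not compare them with other genes. The 10 modification lists (ms2i6A37, t6A37, m1G37, m2A37, unmodified A37, Q34, mnm5s2U34, cmo5U34, acp3U47 and U8) used the loss of depth over a 3-base window. The 14 amino acid lists (branched-chain, beta-branched, aromatic, acidic, amide, basic, small, proline, methionine, class I, class II, rare-codon, queuosine and long variable arm tRNAs) used voom with TMM. Members called are given both adjusted over all species or windows and adjusted over the list alone. With an estimated correlation means camera with the correlation of members estimated from the data, and its preset is 0.01. Camera compares the members of a list with the other species or windows, which is another question than that of fry. Its p is therefore not the fry p corrected for correlation. Position 37 lists in deacylated RNA were compared by exact permutation over species. Shares of depth were compared by exact permutation of 3 against 3 libraries, whose smallest p is 0.1, and by exact sign flips of the 3 differences within replicate numbers, whose smallest p is 0.25. Replicates were compared by Pearson correlation of log2 counts with 1 added and of stop fractions.

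Groups, comparisons, tests, lists, the other settings to be tried and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls among called species together with tRNA-iniMet(CAU) and tRNA-Sec(UCA) in any case. It named up to 8 rises and 8 falls among called stop sites of at least 5 points, the 20 highest stop fractions in deacylated RNA outside the first 2 and last 3 bases, and the 5 non-tRNA genes of the highest depth in deacylated RNA. These settings were DESeq2 1.42.0, library totals without TMM, no filter, all 15 libraries in the fit, a replicate block, mean depth as the count, depth minimums of 20 and 1000, untransformed stop fractions, 3-base windows or single steps, camera, Spearman correlation, a count minimum, shares by reads and leaving out each library. Added after seeing the data were single genes, depth of unannotated copies added to species, a mean of at least 10 stopped reads, tRNA shares paired by replicate number, unannotated stretches counted as tRNA in these shares, and leaving out untreated replicate 1 and DNase replicate 3 together.

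Replicate numbers were checked for pairing by correlating the deviations of libraries of the same number from their group means across species. The correlation was 0.64, 0.69 and 0.18 for oxidized then deacylated with deacylated and 0.41, 0.66 and 0.16 for the 2 oxidized groups, so the numbers were taken to pair there, although replicate 3 of the former (0.44) and replicates 1 and 3 of the latter (0.50 and 0.45) correlated more with another number. In these 2 comparisons, values with a replicate block are given beside the main ones where they changed a call or moved a count by over 1.5 times. In the other 3, where the numbers were not taken to pair, the calls of named species, named sites and lists that the block ended are given too. Other block values of these comparisons are given only with the other settings. This division is a judgement, since the labels number R1 to R3 in every group. For deacylated then oxidized with deacylated, replicates 1 and 2 correlated most with their own number (0.44 against 0.13 and 0.49 against -0.11). More numbers matched there than between the 2 oxidized groups, so the division does not follow a single rule.

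Counts for oxidized then deacylated against deacylated were simulated from a negative binomial with 1 dispersion for all species and changes of 2-fold or 4-fold. On these, edgeR recovered 10 of 10 changed species with 0 others called, which does not show how smaller changes in the real data fare. Limma recovered 48 of 200 simulated sites changed by 2 on the log2 odds scale (24%) with 3 others called among 3009, so most sites changed by that amount were not called. Every simulated site had the same spread, with sampling noise added to an observed spread that already held it. The 24% is therefore not the recovery of the real test. Fry recovered 1 of 1 amino acid list with 1 other called and 1 of 1 modification list with 0 others. Analyses ran in R 4.3.3 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Reads outside annotated genes were not analysed here beyond their share and the stretches described at the end.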

Results

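Transfer RNAs of Escherichia coli K-12 MG1655 were profiled by Dts-seq in 15 libraries made from total RNA of cells in LB medium at 37 °C and an OD600 near 4.0. In this protocol an adapter is ligated to RNA 3' ends, reverse transcription starts from the adapter, and amplification favours cDNA of RNA that ends in CCA, the 3' end of every tRNA. The 5 groups of 3 libraries differed in the treatment of the RNA before ligation. RNA was left untreated, treated with DNase, or treated with DNase and deacylated, which removes the amino acid from charged tRNA (the deacylated group). In the remaining groups the DNase-treated RNA was oxidized and then deacylated, or deacylated and then oxidized. Oxidation of the 3'-terminal ribose blocks ligation, and a bound amino acid shields that ribose. The values are numbers of reads covering each base of each strand of the genome, so they give both the abundance of a tRNA (reads over its 3'-terminal base) and the bases at which reverse transcription ended (loss of depth from a base to its 5' neighbour).

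The reads over the 3'-terminal bases of the 86 tRNA genes numbered 6299378, 5026259 and 6793487 in the untreated libraries and 7056584, 6669155 and 7385009 in the DNase libraries. The deacylated libraries held 8899274, 7301758 and 6598665 such reads. The libraries oxidized then deacylated held 5028620, 6572482 and 8539131, and those deacylated then oxidized held 6268372, 4804363 and 5179468. The genes were summed to 42 tRNA species of the same amino acid and anticodon. Across species, the counts of replicates correlated with r between 0.955 and 0.998, and the stop fractions across positions with r between 0.926 and 0.995. These are correlations across species or positions, which are not independent replicates. Untreated replicate 1 correlated with the other untreated libraries at 0.970 and 0.963, which correlated with each other at 0.997. DNase replicate 3 correlated with the other DNase libraries at 0.957 and 0.955, which correlated with each other at 0.989. Every pair of replicates differed by more than sampling noise, with a chi-square of at least 741 per degree of freedom. Nothing in the sources used here says that replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

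Depth outside tRNA genes was smallest in the oxidized libraries. The sense strand of tRNA genes held 97.4% ± 0.974 (SD, n = 3) of the summed depth in untreated RNA, 97.9% ± 0.188 after DNase and 98.1% ± 0.457 after deacylation. It held 99.3% ± 0.0426 after oxidation then deacylation and 99.2% ± 0.0498 after deacylation then oxidation. The difference was 0.516 points for DNase against untreated (exact permutation test, two-sided, p = 0.5) and 0.145 points for deacylated against DNase (exact p = 0.8). These 2 turned to -0.0132 without untreated replicate 1 and to -0.118 without deacylated replicate 1. The difference was 1.18 points for oxidized then deacylated against deacylated and 1.114 points for deacylated then oxidized against deacylated. Both reached an exact p of 0.1, the smallest that 3 libraries against 3 can give. Counted by reads in place of summed depth these 2 differences were 0.428 and 0.333 points. Not all of this depth need come from other RNA, because 2 unannotated stretches that followed tRNA species over the libraries held 0.911% ± 0.351 of the depth in deacylated RNA, a mean of 47.3% of the depth outside tRNA genes. With these stretches counted as tRNA the 2 differences were 0.742 and 0.582 points (exact p = 0.1 each). The 2 oxidized groups differed by 0.0665 points (exact p = 0.2), and by 0.159 points with the stretches counted as tRNA (exact p = 0.1). So counted, DNase against untreated stood at 0.769 points and deacylated against DNase at -0.0657 points. Ribosomal RNA genes held 0.0713% ± 0.0353 of the depth in deacylated libraries, 0.0059% ± 0.000471 after oxidation then deacylation and 0.0823% ± 0.0149 after deacylation then oxidation.

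The non-tRNA genes of the highest depth in the deacylated libraries were chiZ, ffs, chiP, ssrA and insA7, and their values are the maximum depth within the gene. The ffs gene (chromosome, 476448 to 476561, ASM584v2) encodes the RNA of the signal recognition particle and had 831 ± 411 reads per 1000000 tRNA reads in deacylated libraries, with 853 ± 456 in untreated ones. It had 2.54 ± 0.606 after oxidation then deacylation and 37.6 ± 12 after deacylation then oxidation (SD, n = 3). The chiZ gene (708236 to 708333) encodes a small RNA and had 884 ± 374, 2.84 ± 0.740 and 44.7 ± 9.89 reads per 1000000 tRNA reads in these 3 groups. The values of its neighbour chiP (708334 to 709740), a porin gene whose peak lay beside chiZ, were 316 ± 163, 1.22 ± 0.169 and 17.0 ± 3.59. Those of insA7 (4518527 to 4518802), an insertion sequence gene, were 254 ± 29.6, 1.12 ± 0.155 and 11 ± 2.18. The ssrA gene (2755593 to 2755955) encodes tmRNA, which carries alanine and frees stalled ribosomes. It had 271 ± 175 reads per 1000000 tRNA reads after deacylation, 239 ± 79.0 after oxidation then deacylation and 20.8 ± 8.70 after deacylation then oxidation. Maximum depths of these genes were described and not tested.

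**Figure D1:**
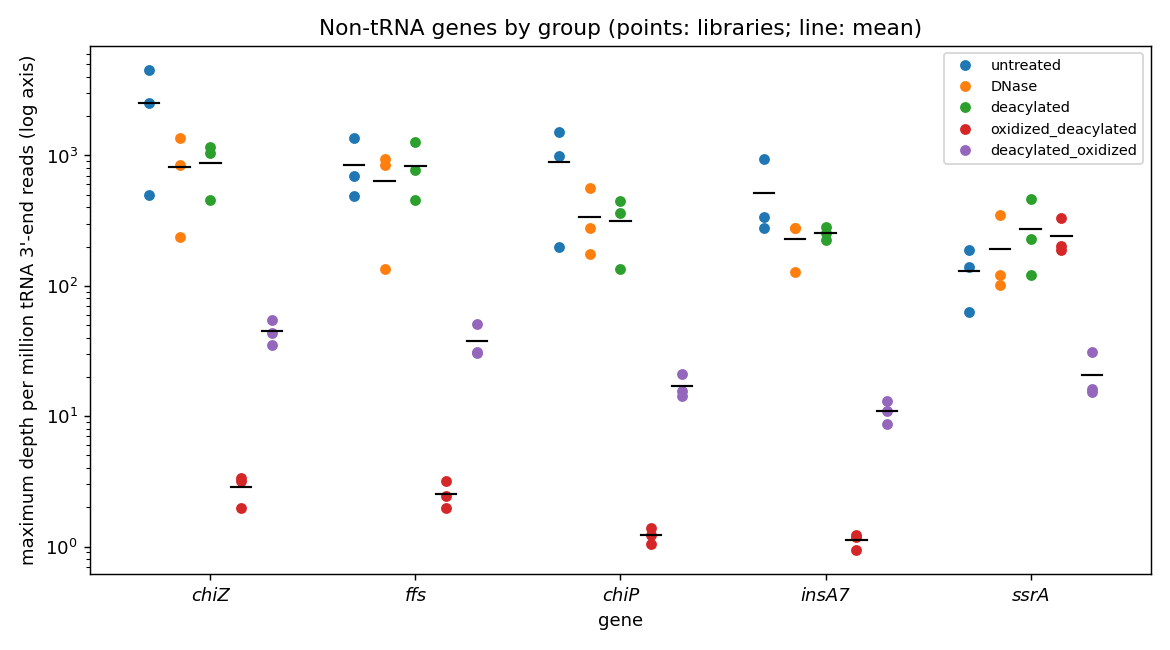
Maximum depth per 1000000 tRNA reads (log axis) for the 5 non-tRNA genes in each of the 15 libraries, with points for libraries and a line at the mean of each group of 3. Means of ffs were 831 after deacylation, 2.54 after oxidation then deacylation and 37.6 after deacylation then oxidation, and those of ssrA were 271, 239 and 20.8.

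The first question was where reverse transcription ended on deacylated tRNA, which includes tRNAs that were charged and uncharged in the cell. Losses of depth were concentrated at modified bases of the anticodon loop and variable loop. Over the 3-base window around position 37, the base 3' of the anticodon, the 8 species with ms2i6A, a methylthiolated isopentenyl adenosine, lost 97.5% ± 2.62 (SD over species) of the depth. The 7 species with m1G, a methylation of the pairing face, lost 90.9% ± 17.8, with the lowest value of 50.8% in tRNA-Leu(UAG). The 11 species with t6A, threonylcarbamoyl adenosine, lost 33.6% ± 25.1, from 8.18% in tRNA-Ser(GCU) to 73.7% in tRNA-Thr(GGU). The 6 species with m2A lost 3.56% ± 4.17 and the 8 species with an unmodified adenosine lost 4.39% ± 3.85. Against unmodified adenosine, permutation tests over species (two-sided, exact, over 4 lists) gave an adjusted p of 0.000311 for ms2i6A, 0.000311 for m1G, 0.00492 for t6A and 0.698 for m2A. With the single step at base 37 in place of the window, the difference for t6A went from 29.2 points to 3.01 points (adjusted permutation p = 0.393).

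Outside position 37, the 7 species with acp3U at position 47 of the variable loop had a median loss of 96.7%, from 79.2% in tRNA-Val(GAC) to 99.4% in tRNA-Met(CAU). At position 34, the wobble base, the median was 76.2% for the 6 species with cmo5U, 27.9% for the 3 with mnm5s2U and 9.21% for the 4 with queuosine. The lists spread widely, from 5.98% in tRNA-Val(UAC) to 97.4% in tRNA-Thr(UGU) for cmo5U and from 4.68% in tRNA-Asp(GUC) to 78.9% in tRNA-Tyr(GUA) for queuosine. The 31 species measured at U8, the site of 4-thiouridine, had a median of 2.44%, with up to 17.7% in tRNA-Cys(GCA).

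Among single bases counted from the 5' end, without the first 2 and last 3 bases of each tRNA, 12 of the 20 highest stop fractions lay within 1 base of position 37, 5 within 1 base of position 47 and 3 within 1 base of position 34. The highest was 99.6% ± 0.126 (SD, n = 3) at base 38 of tRNA-Pro(CGG), with 99.6% ± 0.0797 in untreated RNA. It was followed by base 38 of tRNA-Leu(CAA) at 99.1% ± 0.771 and of tRNA-Tyr(GUA) at 97.7% ± 2.19, with 99.4% and 98.6% in untreated RNA. Base 34 of tRNA-Ile(CAU), the lysidine tRNA that reads AUA codons, stood at 97.7% ± 1.22 against 92.2% ± 1.27 in untreated RNA. The others were tRNA-Arg(CCG) base 38, tRNA-Thr(UGU) base 34, tRNA-Met(CAU) base 48, tRNA-Leu(UAA) base 38, tRNA-Arg(ACG) base 48, tRNA-Arg(UCU) base 35, tRNA-Phe(GAA) bases 47 and 37, tRNA-Pro(UGG) base 38, tRNA-Leu(GAG) and tRNA-Leu(CAG) base 39, tRNA-Ser(UGA) base 38, tRNA-Ile(CAU) base 47, tRNA-Ile(GAU) base 48, tRNA-Cys(GCA) base 36 and tRNA-Trp(CCA) base 37. Their stop fractions lay between 92.7% and 97.2%. Among the end bases left out, 3 stood as high, base 1 of tRNA-Asn(GUU) at 98.9% ± 0.140, of tRNA-Gln(CUG) at 98.1% ± 1.43 and of tRNA-Gln(UUG) at 98.1% ± 1.33.

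The comparison of DNase-treated with untreated RNA asked whether DNase treatment alters the tRNA profile. Both isoleucine tRNAs rose. The share of tRNA-Ile(CAU), which reads the rare AUA codon (ileX, 3215598 to 3215673; ileY, 2785762 to 2785837), was 0.319% ± 0.0791 of tRNA reads after DNase against 0.121% ± 0.0038 in untreated RNA (SD, n = 3 each), and its TMM-scaled log2 fold was 1.49 ± 0.26 (SE). The share of tRNA-Ile(GAU), the major isoleucine tRNA encoded in ribosomal RNA operons (ileT, 4037141 to 4037217; ileU, 3427076 to 3427152; ileV, 225381 to 225457), was 7.42% ± 2.02 against 3.77% ± 0.0423, with a TMM-scaled log2 fold of 1.07 ± 0.20. Initiator tRNA-iniMet(CAU) stood at a log2 fold of 0.68 ± 0.32 (adjusted p = 0.297) and tRNA-Sec(UCA), the selenocysteine tRNA, at 0.22 ± 0.31 (adjusted p = 0.685), and neither passed the test. By amino acid, the 7 tRNAs for the beta-branched residues isoleucine, valine and threonine rose on balance (fry adjusted p = 0.0366, with 2 of 7 called over all species and 4 adjusted over the list alone, and adjusted p = 0.417 with an estimated correlation). Camera at the preset correlation called only this list (adjusted p = 0.0022). The 3 proline tRNAs fell on balance with 0 members called over all species or adjusted over the list alone (adjusted p = 0.0366; adjusted p = 0.417 with an estimated correlation).

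The acidic list (0 of 2 called), the class I synthetase list (2 of 21 called, 4 adjusted over the list alone) and the rare-codon list (1 of 7 called, 1 adjusted over the list alone) rose on balance, each with a fry adjusted p of 0.0372. With an estimated correlation the adjusted p was 0.521 for the acidic list, 0.417 for class I and 0.521 for rare codons. The other 9 amino acid lists had adjusted p-values of 0.140 or more. For the small, aromatic, basic and class II lists the median, mean and test did not share a sign.

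In total 2 of 42 species rose and 0 fell after DNase (edgeR quasi-likelihood test, adjusted p = 0.0194 for both). Unadjusted p was under 0.05 for 8, and DESeq2 called 4. The raw shares of the groups, which depend on each other, did not overlap for 13 of 42 species, where chance gives 10%. Among these were tRNA-Lys(UUU) and tRNA-Pro(GGG), whose TMM-scaled folds were not called by edgeR (adjusted p = 0.511 each). No stop site of 2979 passed limma's test (279 with an unadjusted p under 0.05, 49 called when all 15 libraries shared a fit), and fry called 0 of 10 modification lists (0 with an unadjusted p under 0.05, 0 with camera at either correlation; lowest adjusted p = 0.340). Both isoleucine calls ended when any untreated replicate or DNase replicate 1 was left out (highest adjusted p = 0.118), at log2 folds between 1.04 and 1.07 for tRNA-Ile(GAU) and between 1.45 and 1.52 for tRNA-Ile(CAU), and without DNase replicate 3 the counts were 6 species, among them tRNA-iniMet(CAU) at 0.80 (adjusted p = 0.0464), 5 sites, 2 modification lists and 3 amino acid lists. The 5 amino acid lists went to 0 without any other single library and to 0 without TMM, and without untreated replicate 1 and DNase replicate 3 together, the pair that stood apart, 6 species and 71 sites were called. With the replicate number as a block, edgeR called 0 species and fry 0 amino acid lists. The block left tRNA-Ile(CAU) at 1.47 (adjusted p = 0.131) and tRNA-Ile(GAU) at 1.04 (adjusted p = 0.0803).

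The comparison of deacylated with DNase-treated RNA addressed whether removing amino acids changes which tRNAs were captured. No species passed the test. The lowest folds were those of tRNA-Asn(GUU), at 3.77% ± 1.30 of tRNA reads against 7.93% ± 4.96 (log2 fold -1.10 ± 0.47 SE, n = 3 each), and of tRNA-Gly(GCC), at 0.774% ± 0.471 against 1.61% ± 0.528 (log2 fold -1.08 ± 0.43), both with an adjusted p of 0.627. These 2 species were chosen after their values were seen. Without DNase replicate 3 they stood at -0.48 and -0.77 (adjusted p = 0.934 and 0.872), and without deacylated replicate 1 tRNA-Gly(GCC) stood at -1.70 (adjusted p = 0.0605). The initiator tRNA-iniMet(CAU) stood at 0.25 ± 0.33 and tRNA-Sec(UCA) at -0.29 ± 0.23 (adjusted p = 0.722 each). The edgeR test called 0 of 42 species, with 1 at an unadjusted p under 0.05, and DESeq2 called 0, with 5 at an unadjusted p under 0.05. The raw shares of the groups did not overlap for 1 species.

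Among 2968 sites, limma called 1 (242 with an unadjusted p under 0.05): base 62 of tRNA-Asn(GUU), chosen after its value was seen, at 0.0356% of reads against 0 (adjusted p = 0.00722). No called site moved by 5 points or more. Of the 10 modification lists fry called 0 (0 with an unadjusted p under 0.05; lowest adjusted p = 0.317), while camera with a preset correlation of 0.01 called 3, the ms2i6A, t6A and m1G lists at position 37, all downward; with an estimated correlation camera called 0 (adjusted p = 0.530 for each). Fry called 0 of 14 amino acid lists (0 with an unadjusted p under 0.05; lowest adjusted p = 0.526), and camera called 1 with the preset and 0 with an estimated correlation. For the aromatic and basic lists the median, mean and test did not share a sign. The call at base 62 ended without DNase replicate 1 or any deacylated replicate, there were 4 calls without DNase replicate 2, and 1 modification list was called without deacylated replicate 1. With the replicate number as a block 0 sites were called, and 2 species were called down.

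Oxidation before deacylation is meant to block the ligation of uncharged tRNA, so that its comparison with deacylated RNA contrasts charged tRNA with all tRNA, and how complete the block was is not stated. The 4 serine tRNAs and tRNA-Thr(UGU) had the largest falls. The share of tRNA-Ser(UGA), which reads UCA codons (serT, 1031625 to 1031712), was 0.0868% ± 0.00802 against 0.887% ± 0.0736 in deacylated RNA, and its TMM-scaled fold was 10.4-fold lower (log2 fold -3.37 ± 0.17 SE, n = 3 each). The scaled falls of tRNA-Ser(CGA), tRNA-Ser(GCU) and tRNA-Ser(GGA) were 6.44-fold, 5.28-fold and 3.65-fold. The share of tRNA-Thr(UGU) (thrU, 4175388 to 4175463) was 3.72% ± 0.410 against 10.8% ± 4.09, with a scaled fall of 3.03-fold. The largest rises were those of tRNA-Asn(GUU) (asnT, 2044549 to 2044624, and 3 further genes), at 11% ± 2.53 against 3.77% ± 1.30, and of tRNA-Glu(UUC), at 1.14% ± 0.0939 against 0.409% ± 0.153, with scaled folds of 2.81 and 2.79.

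The other named rises in log2 fold were tRNA-Gly(CCC) 1.24 ± 0.21, tRNA-Gly(UCC) 1.14 ± 0.19, tRNA-Val(UAC) 1.12 ± 0.16, tRNA-Ala(GGC) 0.92 ± 0.18, tRNA-Ala(UGC) 0.87 ± 0.19, tRNA-Gln(UUG) 0.80 ± 0.22, tRNA-His(GUG) 0.78 ± 0.16 and tRNA-iniMet(CAU) 0.73 ± 0.18. The other falls were tRNA-Arg(UCU), which reads the rare AGA codon, at -1.03 ± 0.33, tRNA-Pro(UGG) at -0.84 ± 0.15, tRNA-Cys(GCA) at -0.57 ± 0.17 and tRNA-Pro(CGG) at -0.52 ± 0.14. For tRNA-Sec(UCA) the log2 fold was 0.28 ± 0.20 and did not pass the test (adjusted p = 0.321; 0.47 with an adjusted p of 0.0274 without deacylated replicate 2). In total 11 of 42 species rose and 9 fell (edgeR, adjusted p between 2.11e-06 and 0.0498), and DESeq2 called 22. The raw shares of the groups, which depend on each other, did not overlap for 21, where chance gives 10%. The call of tRNA-Arg(UCU) ended without any of 5 libraries, at a log2 fold of -0.59 and an adjusted p of 0.0909 without deacylated replicate 3. Those of tRNA-Cys(GCA) and tRNA-Pro(CGG) ended without oxidized then deacylated replicate 3 (adjusted p = 0.188 and 0.130) and without replicate 2 of that group, where tRNA-Pro(CGG) stood at -0.33. The call of tRNA-Cys(GCA) also ended without replicate 1 of that group, without TMM (adjusted p = 0.0791) and with all 15 libraries in the fit (adjusted p = 0.278), that of tRNA-His(GUG) with that fit (adjusted p = 0.0754) and that of tRNA-iniMet(CAU) with mean depth as the count (0.49, adjusted p = 0.0629).

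By amino acid, 8 of 14 lists were called in oxidized then deacylated against deacylated RNA. The small list of glycine, alanine and serine tRNAs fell on balance (adjusted p = 0.00059), although 4 of its 9 members rose and 4 fell and its median log2 fold of 0.52 and mean of -0.63 differed in sign. The long variable arm list fell (adjusted p = 0.00456), with the 4 serine tRNAs as the called members among 11. The 3 proline tRNAs fell (2 called, adjusted p = 0.0251) and class II fell (6 of 20 rose and 7 fell, adjusted p = 0.0276). The lists that rose were acidic (1 of 2, adjusted p = 0.0122), amide (2 of 3, adjusted p = 0.0148), methionine (1 of 2, adjusted p = 0.0251) and queuosine tRNAs (2 of 4, adjusted p = 0.0360). Every one of the 8 lists had an adjusted p of 0.794 with an estimated correlation. Members called, adjusted over the list alone, were as many as over all species in these 8 lists. The branched-chain, beta-branched, aromatic, basic, class I and rare-codon lists had adjusted p-values between 0.0768 and 0.841, and the branched-chain, basic and rare-codon lists differed in sign between median, mean and test. With the replicate number as a block 5 lists were called, since amide, methionine and queuosine tRNAs (adjusted p = 0.0525 each) and class II (adjusted p = 0.132) were not, and class I was called up (adjusted p = 0.0151). Leaving out deacylated replicate 1, oxidized then deacylated replicate 1 or replicate 3 of that group gave 4, 3 and 2 lists, and methionine was lost without TMM (adjusted p = 0.248).

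Stop fractions after oxidation then deacylation rose far more often than they fell. Among 3009 positions, 132 rose and 7 fell by at least 5 points (limma, adjusted p under 0.05). The largest rise was at base 33 of tRNA-Asn(GUU), beside the queuosine of the wobble position, from 5.65% ± 2.34 to 81.5% ± 16.6 (SD, n = 3 each). Base 35 of tRNA-Glu(UUC), the wobble position with mnm5s2U, rose from 0.414% ± 0.0361 to 33.8% ± 13.7, and base 36 from 27.4% ± 5.71 to 63.8% ± 13. Base 35 of tRNA-Leu(UAG) rose from 43.4% ± 3.96 to 86.1% ± 4.93, base 32 from 18.2% ± 9.60 to 56.0% ± 6.88 and base 10 from 0.229% ± 0.397 to 34.9% ± 35.4. Base 39 of tRNA-Thr(GGU), in the anticodon stem, rose from 0.162% ± 0.0478 to 30.0% ± 1.32, and base 4 of tRNA-Val(UAC), in the acceptor stem, from 2.26% ± 0.614 to 32.8% ± 4.90. The 7 falls were 5 sites of tRNA-Arg(UCU), of which base 32 went from 69.9% ± 23.3 to 6.53% ± 1.73 and base 33 from 88.6% ± 4.89 to 39.9% ± 6.51, with bases 31, 34 and 9 falling by less, where the mean depth in deacylated libraries was 53.7 at base 31 and 27.3 at base 9. They also included base 76 of tRNA-Ser(GGA), from 22.5% ± 20.3 to 2.44% ± 1.22, and base 34 of tRNA-Cys(GCA), from 16.1% ± 4.82 to 5.89% ± 0.895.

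At any size of change, 816 sites rose and 42 fell, in 42 of 42 species. Of these calls 77 had 0 stops in all 6 libraries and 198 a mean under 10 stopped reads, where the offset of 0.5 turns a change of depth into a change of the logit, and with a mean of at least 10 stopped reads 736 rose and 27 fell of 1792. Leaving out 1 library ended the call of tRNA-Glu(UUC) base 36 (3 of the 6 libraries, highest adjusted p = 0.0668 without oxidized then deacylated replicate 1), of tRNA-Leu(UAG) base 32 (2 of 6, 0.0709 without the same library) and base 10 (1 of 5, 0.0586 without deacylated replicate 3), of tRNA-Arg(UCU) base 9 (2 of 5, 0.0590 without oxidized then deacylated replicate 3) and base 34 (6 of 6, 0.136 without replicate 1 of that group), of tRNA-Ser(GGA) base 76 (5 of 6, 0.0986 without replicate 2 of that group) and of tRNA-Cys(GCA) base 34 (4 of 6, 0.0912 without replicate 1 of that group). Without deacylated replicate 3 the change at base 9 of tRNA-Arg(UCU) went from -9.29 to -2.33 points and at base 76 of tRNA-Ser(GGA) from -20.0 to -8.59 points, and without oxidized then deacylated replicate 1 that at base 10 of tRNA-Leu(UAG) from 34.6 to 14.6 points.

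**Figure D2:**
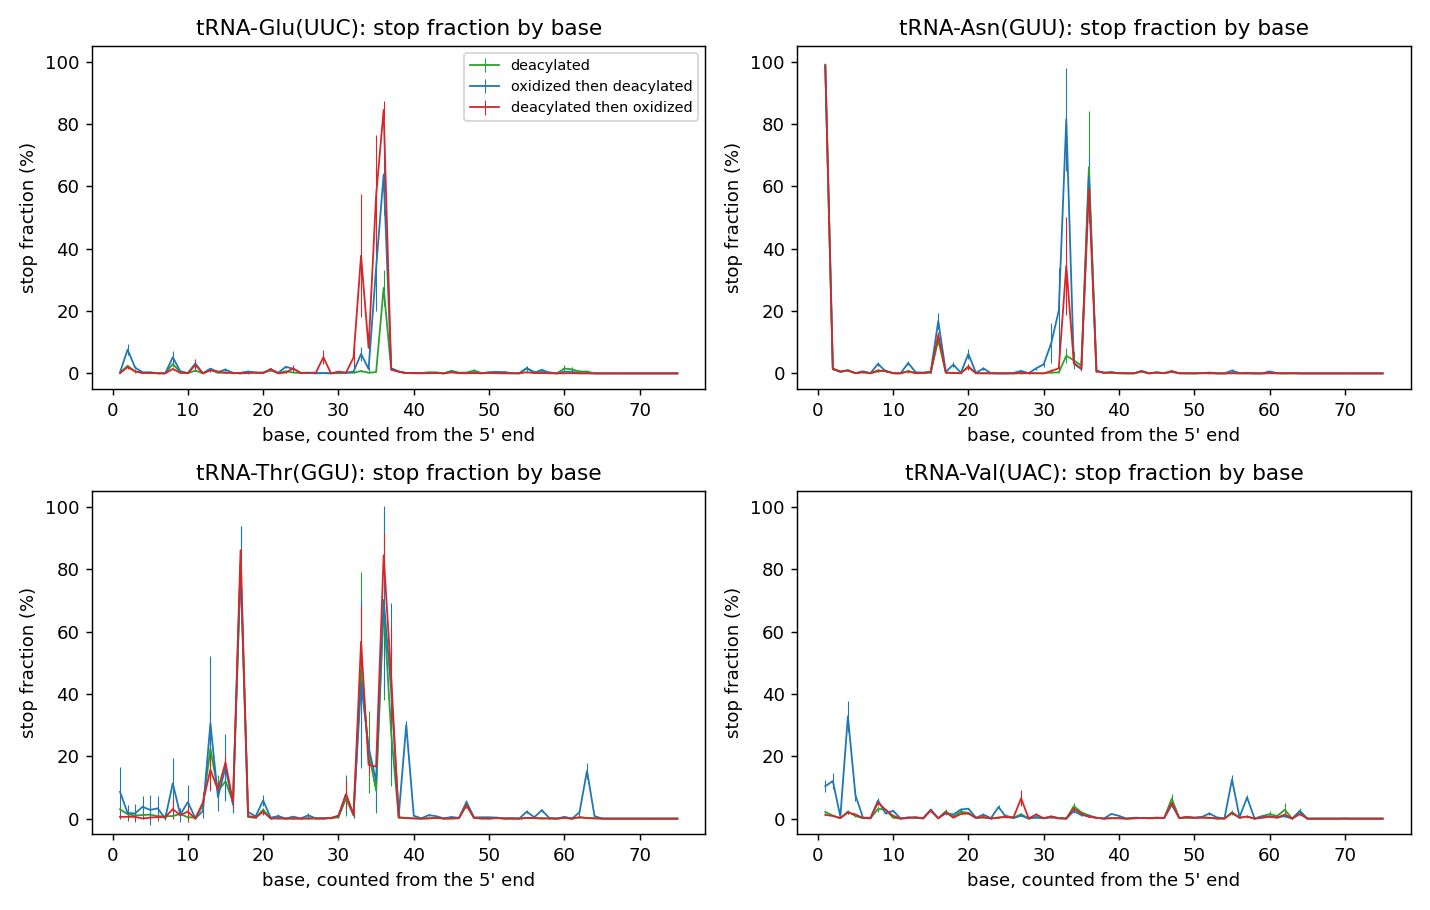
Stop fraction in percent against the base counted from the 5' end for tRNA-Glu(UUC), tRNA-Asn(GUU), tRNA-Thr(GGU) and tRNA-Val(UAC), with lines for the mean and bars for the SD of 3 libraries in the deacylated, oxidized then deacylated, and deacylated then oxidized groups. Base 39 of tRNA-Thr(GGU) stood at 30.0% and base 4 of tRNA-Val(UAC) at 32.8% after oxidation then deacylation, against 0.188% and 1.98% after deacylation then oxidation.

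Of the 10 modification lists, fry called 4 up after oxidation then deacylation. Stops rose widely here, at 1304 of 2943 3-base windows over all bases, and fry does not compare a list with other windows. At U8, the site of 4-thiouridine, 21 of 32 species rose over all sites (22 adjusted over the list alone) and the median loss was 7.69% against 2.53% (fry adjusted p = 0.00256; adjusted p = 0.230 with an estimated correlation). Examples were tRNA-Cys(GCA) at 48% ± 5.25 against 17.7% ± 5.58 and tRNA-iniMet(CAU) at 12.6% ± 2.89 against 1.71% ± 0.278. In the mnm5s2U34 list 1 of 3 rose, tRNA-Glu(UUC) at 77.5% ± 2.94 against 27.9% ± 5.74 (2 adjusted over the list alone; list adjusted p = 0.0115; adjusted p = 0.601 with an estimated correlation). In the Q34 list 2 of 4 rose, tRNA-Asn(GUU) at 82.5% ± 15.4 against 11.8% ± 5.13 and tRNA-His(GUG) at 35.2% ± 2.78 against 6.61% ± 3.65 (2 adjusted over the list alone; list adjusted p = 0.0269; adjusted p = 0.559 with an estimated correlation). The m2A37 list rose with 2 of 6 members called (3 adjusted over the list alone; adjusted p = 0.0296; adjusted p = 0.601 with an estimated correlation), among them tRNA-Gln(CUG) at 4.77% ± 0.860 against 0.941% ± 0.276. The unmodified A37 list, with 2 members down, had an adjusted p of 0.0618, and the ms2i6A37, t6A37, m1G37, cmo5U34 and acp3U47 lists had values between 0.722 and 0.928, with a median of -0.46 and a mean of 0.01 for cmo5U34. With the replicate number as a block m2A37 was not called (adjusted p = 0.198) and unmodified A37 was called down (adjusted p = 0.0270), which gave 3 lists up and 1 down. The count of 4 lists went to 1 without oxidized then deacylated replicate 3. Camera at the preset correlation called U8 up (adjusted p = 2.46e-09) and unmodified A37 down (adjusted p = 0.00273). It did not call mnm5s2U34, Q34 or m2A37 (adjusted p = 0.457, 0.253 and 0.457).

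Deacylation before oxidation is meant to leave no amino acid as a shield, although the labels do not state how complete it was, and its comparison with deacylated RNA shows what remains ligatable after both steps. Isoleucine, valine, glutamate and initiator methionine tRNAs made up far more of the reads. The share of tRNA-Ile(GAU) was 32.8% ± 1.29 against 10.2% ± 1.1 in deacylated RNA, with a TMM-scaled fold of 4.68 (log2 fold 2.23 ± 0.09 SE, n = 3 each). The scaled rises of tRNA-Val(UAC), tRNA-Glu(UUC), tRNA-Ile(CAU), tRNA-iniMet(CAU) and tRNA-Val(GAC) were 5.74-fold, 5.69-fold, 4.96-fold, 4.32-fold and 4.01-fold. The 3 proline tRNAs and tRNA-Asn(GUU) fell most. The share of tRNA-Pro(CGG) (proK, 3708616 to 3708692) was 0.189% ± 0.0454 against 4.64% ± 0.181, and that of tRNA-Asn(GUU) was 0.174% ± 0.0561 against 3.77% ± 1.30, with scaled falls of 16.9-fold and 15.2-fold.

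The remaining named rises in log2 fold were tRNA-Thr(CGU) 1.43 ± 0.36, tRNA-His(GUG) 1.32 ± 0.14, tRNA-Thr(GGU) 1.24 ± 0.24 and tRNA-Gln(UUG) 1.07 ± 0.23. The remaining named falls were tRNA-Pro(UGG) -3.98 ± 0.19, tRNA-Pro(GGG) -3.77 ± 0.28, tRNA-Arg(CCG) -2.91 ± 0.21, tRNA-Ala(GGC) -2.72 ± 0.19, tRNA-Arg(CCU) -2.62 ± 0.30, tRNA-Arg(UCU) -2.53 ± 0.31, tRNA-Ala(UGC) -2.26 ± 0.21 and tRNA-Arg(ACG) -2.20 ± 0.18. In total 13 species rose and 21 fell of 42 (edgeR, adjusted p between 7.44e-08 and 0.0297), and DESeq2 called 38. The raw shares of the groups did not overlap for 37, where chance gives 10%. These shares depend on each other, as tRNA-Ile(GAU) alone held 32.8% of the reads after deacylation then oxidation. The log2 fold of tRNA-Sec(UCA) was 0.32 ± 0.20 (adjusted p = 0.180), with a call at 0.76 by DESeq2 (adjusted p = 0.000181) and at 0.61 without deacylated replicate 2 (adjusted p = 0.0136). All folds are relative to TMM scaling and differ from ratios of the raw shares. The median log2 fold of all species was -0.43 with TMM and shifted by -0.54 without TMM, which gave 10 rises and 25 falls, and by 0.42 with DESeq2, which gave 20 rises and 18 falls. Without TMM the smaller rises of tRNA-Thr(UGU), tRNA-Trp(CCA) and tRNA-Tyr(GUA) were not called and tRNA-Cys(GCA), tRNA-Lys(UUU), tRNA-Met(CAU) and tRNA-Phe(GAA) were called down. With DESeq2 the smaller falls of tRNA-Gln(CUG), tRNA-Gly(CCC) and tRNA-Ser(GCU) were not called, and those 4 species, tRNA-Asp(GUC), tRNA-Gly(UCC) and tRNA-Sec(UCA) were called up.

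**Figure D3:**
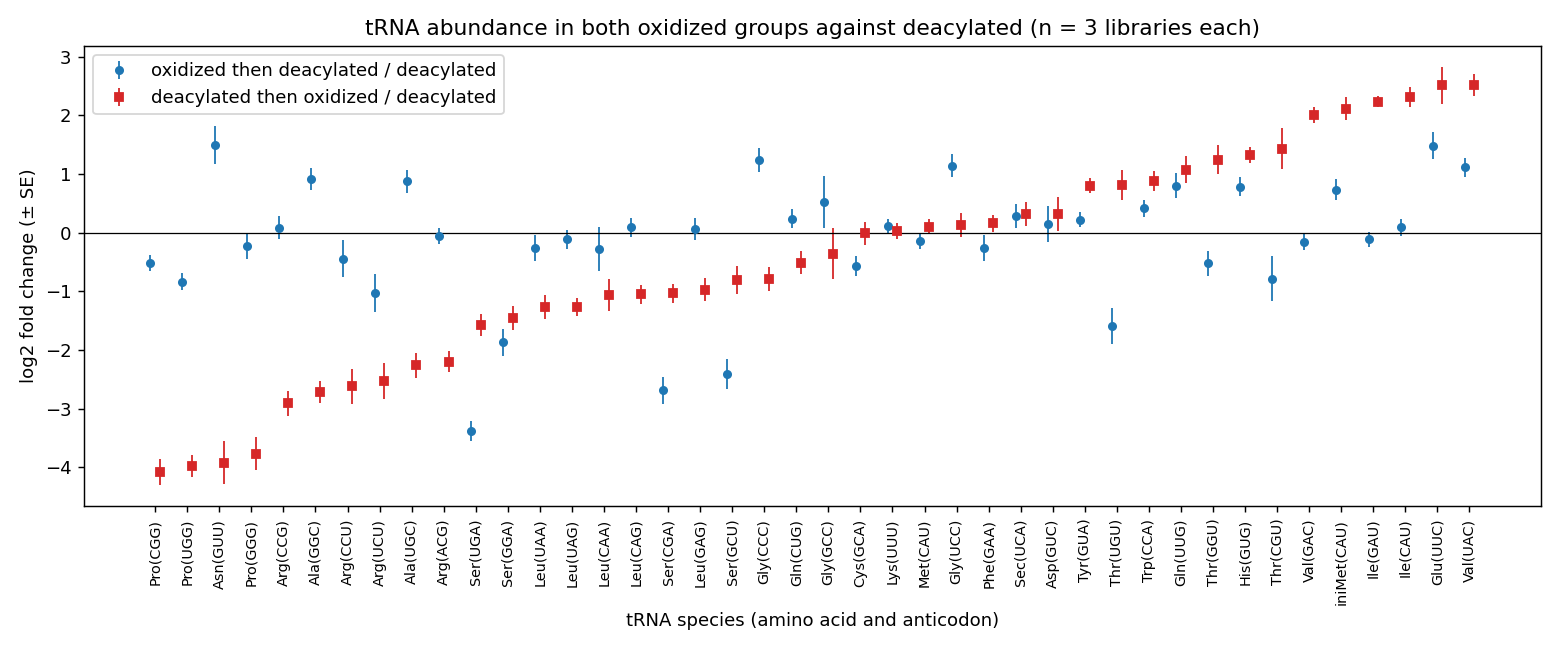
TMM-scaled log2 fold change of tRNA reads for each of the 42 tRNA species, oxidized then deacylated over deacylated and deacylated then oxidized over deacylated (n = 3 libraries each), with points for the edgeR estimate and bars for its SE. The value of tRNA-Ser(UGA) was -3.37 after oxidation then deacylation, and that of tRNA-Pro(CGG) was -4.08 after deacylation then oxidation.

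By amino acid, 13 of 14 lists were called in deacylated then oxidized against deacylated RNA, and the queuosine tRNAs were not (adjusted p = 0.116; median 0.56, mean -0.37). All 7 beta-branched tRNAs rose (adjusted p = 6.32e-05, and adjusted p = 0.139 with an estimated correlation). Camera at the preset correlation called only this list (adjusted p = 0.000797). The 3 proline tRNAs fell and 7 of 9 small ones fell (adjusted p = 0.000121 each), and 4 of 6 basic, 6 of 7 rare-codon and 9 of 11 long variable arm tRNAs fell (adjusted p = 0.000142 each), with 1 member of each of these 3 lists rising. Class II fell (11 down and 4 up of 20, adjusted p = 0.000198), while aromatic (2 of 3 up, adjusted p = 0.00016), methionine (1 of 2 up, adjusted p = 0.000664) and acidic (1 of 2 up, adjusted p = 0.00184) rose. The adjusted p of each of these 9 lists was 0.399 with an estimated correlation. Branched-chain was called up with 4 members up and 5 down (adjusted p = 0.00016; median -0.97, mean 0.38; adjusted p = 0.436 with an estimated correlation), as the isoleucine and valine tRNAs rose and the leucine tRNAs fell. The amide list fell (2 down and 1 up of 3, adjusted p = 0.00329; adjusted p = 0.792 with an estimated correlation). Class I was called up with 9 up and 10 down of 21 (adjusted p = 0.00374; median -0.01, mean 0.01; adjusted p = 0.399 with an estimated correlation), and without TMM it was called down (adjusted p = 0.0175). With the replicate number as a block class I was not called (fry adjusted p = 0.05003). Without TMM the branched-chain, aromatic and methionine lists were not called (adjusted p = 0.458, 0.450 and 0.0677). Members called, adjusted over the list alone, were as many as over all species in every list.

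At stop sites, 29 positions rose and 8 fell by at least 5 points after deacylation then oxidation. In tRNA-Glu(UUC) base 36 rose from 27.4% ± 5.71 to 84.5% ± 2.74, base 35 from 0.414% ± 0.0361 to 57.1% ± 19.3 and base 33 from 0.764% ± 0.217 to 37.8% ± 19.7 (SD, n = 3 each). Base 34 of tRNA-Gln(UUG), the wobble neighbourhood, rose from 52.5% ± 18.1 to 92.0% ± 2.95, and base 34 of tRNA-Gly(UCC) from 12.6% ± 4.56 to 50.1% ± 9.68. In tRNA-Leu(UAG) base 35 rose from 43.4% to 83.5% ± 5.27 and base 32 from 18.2% to 55.8% ± 6.31, and base 32 of tRNA-Lys(UUU) rose from 5.09% ± 1.65 to 37.3% ± 21.8. Base 45 of tRNA-Arg(ACG) fell from 79.1% ± 5.64 to 18.6% ± 6.98, with falls at its bases 42 and 2. In tRNA-Arg(UCU) base 32 fell from 69.9% to 6.87% ± 3.84 and base 33 from 88.6% to 47.7% ± 6.64. Base 47 of tRNA-Lys(UUU), its acp3U, fell from 84.4% ± 5.30 to 61.5% ± 4.85, with a fall at base 46, and base 34 of tRNA-Cys(GCA) fell from 16.1% to 5.82% ± 1.68.

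At any size, limma called 525 rises and 170 falls of 2949 sites in deacylated then oxidized against deacylated RNA, but 364 of these 695 had 0 stops in all 6 libraries and 522 a mean under 10 stopped reads. With a mean of at least 10 stopped reads 67 rose and 65 fell of 1527, and limma on the untransformed fraction called 7 rises and 19 falls. Leaving out 1 library ended the call of tRNA-Leu(UAG) base 32 (3 of 6 libraries, highest adjusted p = 0.0858 without deacylated then oxidized replicate 1), of tRNA-Lys(UUU) base 32 (4 of 6, 0.0689 without deacylated replicate 1), base 47 (4 of 6, 0.0835 without deacylated then oxidized replicate 2) and base 46 (5 of 6, 0.122 without the same library), and of tRNA-Cys(GCA) base 34 (5 of 6, 0.135 without deacylated replicate 3). The change at base 32 of tRNA-Lys(UUU) went from 32.2 to 20.3 points without deacylated then oxidized replicate 2 and at base 46 from -13.7 to -8.17 points without deacylated replicate 2. With the replicate number as a block, limma did not call base 34 of tRNA-Cys(GCA) (adjusted p = 0.0624) or base 46 of tRNA-Lys(UUU) (adjusted p = 0.0795). Of the 29 rises of at least 5 points 2 had a mean depth under 100 in a group, and both turned without 1 library, and of the 8 falls 1 had such a depth, base 2 of tRNA-Arg(ACG).

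Fry called 0 of 10 modification lists here (4 with an unadjusted p under 0.05; 3 with camera at the preset correlation, 0 at an estimated one). The lowest adjusted p was 0.0535 for mnm5s2U34, where 2 of 3 members rose (2 adjusted over the list alone), tRNA-Glu(UUC) to 93.7% ± 3.73 from 27.9% ± 5.74 and tRNA-Gln(UUG) to 93.1% ± 3.30 from 53.6% ± 18.2. U8 (5 of 30 up, 8 adjusted over the list alone) and Q34 (1 of 4 up, 2 adjusted over the list alone, with tRNA-His(GUG) at 34% ± 3.74 against 6.61% ± 3.65) had an adjusted p of 0.0636. For the m2A37 and acp3U47 lists the test pointed up while median and mean were negative. Without deacylated replicate 1 or without deacylated then oxidized replicate 3, 1 list was called.

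The direct comparison of the 2 orders of treatment holds the reagents constant and contrasts oxidation before deacylation with oxidation after it. The asparagine, alanine and proline tRNAs were higher when oxidation came before deacylation. The TMM-scaled fold was 45.4 for tRNA-Asn(GUU) (log2 fold 5.50 ± 0.31 SE, n = 3 each), 13.1 for tRNA-Ala(GGC), 12.5 for tRNA-Pro(CGG), 12.3 for tRNA-Pro(GGG), 9.29 for tRNA-Pro(UGG) and 9.15 for tRNA-Ala(UGC). It was 8.35 for tRNA-Arg(CCG), 4.81 for tRNA-Arg(CCU), 4.63 for tRNA-Arg(ACG) and 4.24 for tRNA-Gly(CCC). The threonine, isoleucine and valine tRNAs were lower, with tRNA-Thr(UGU) at 3.72% ± 0.410 against 13.2% ± 1.73 and tRNA-Ile(GAU) at 9.51% ± 0.723 against 32.8% ± 1.29, and scaled falls of 5-fold and 4.85-fold.

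The other named falls in log2 fold were tRNA-Ile(CAU) -2.16 ± 0.17, tRNA-Thr(CGU) -2.13 ± 0.23, tRNA-Val(GAC) -2.09 ± 0.16, tRNA-Ser(UGA) -1.74 ± 0.17, tRNA-Thr(GGU) -1.69 ± 0.22, tRNA-Ser(CGA) -1.59 ± 0.25, tRNA-Ser(GCU) -1.53 ± 0.14, tRNA-Val(UAC) -1.35 ± 0.19 and tRNA-iniMet(CAU) -1.31 ± 0.17. In total 19 species were higher and 16 lower of 42 (edgeR, adjusted p between 3.67e-09 and 0.0311), and DESeq2 called 37. The raw shares of the groups, which depend on each other, did not overlap for 34, where chance gives 10%. The median log2 fold shifted by 0.50 without TMM, which gave 22 higher and 11 lower, and the smaller falls of tRNA-Cys(GCA), tRNA-Glu(UUC), tRNA-His(GUG), tRNA-Trp(CCA) and tRNA-Tyr(GUA) were then not called, with tRNA-His(GUG) at 0.03 and tRNA-Trp(CCA) at 0.10, while tRNA-Lys(UUU), tRNA-Met(CAU) and tRNA-Sec(UCA) were called up. DESeq2 called tRNA-Met(CAU) down (-0.22, adjusted p = 0.0108). For tRNA-Sec(UCA) the log2 fold was 0.02 ± 0.22 (adjusted p = 0.928), and 0.52 with a call without TMM (adjusted p = 0.00853).

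Of the amino acid lists, 12 of 14 were called between the 2 orders of treatment. The 7 beta-branched tRNAs were all lower (adjusted p = 0.000132; adjusted p = 0.506 with an estimated correlation), while proline (3 of 3), amide (2 of 3), basic (4 up and 1 down of 6) and rare-codon (6 up and 1 down of 7) tRNAs were higher, each at an adjusted p of 0.000132 (0.843 for amide and adjusted p = 0.708 for the other 3 with an estimated correlation). Class II (9 up and 7 down of 20, adjusted p = 0.00412), small (5 up and 3 down of 9, adjusted p = 0.0103) and queuosine tRNAs (1 up and 2 down of 4, adjusted p = 0.0418; median -0.29, mean 1.10) were called up, each at an adjusted p of 0.933 with an estimated correlation. Methionine (1 of 2 down, adjusted p = 0.00221), aromatic (2 of 3 down, adjusted p = 0.0309), branched-chain (5 up and 4 down of 9, adjusted p = 0.0333; median 0.83, mean -0.27) and acidic (1 of 2 down, adjusted p = 0.0333) were called down. Their adjusted p with an estimated correlation was 0.843, 0.856, 0.933 and 0.856. Class I (adjusted p = 0.139; median -0.18, mean 0.16) and long variable arm (adjusted p = 0.740; median 0.02, mean -0.02) were not called. Without TMM branched-chain was not called (adjusted p = 0.651), and the aromatic and acidic lists pointed up and were not called (adjusted p = 0.589 and 0.848). Class I and long variable arm were then called up (adjusted p = 0.00013 and 0.00258). Camera at the preset correlation called only the beta-branched list, downward (adjusted p = 0.000954). With the replicate number as a block 8 lists were called, 6 up and 2 down, and the lists lost were branched-chain and acidic (adjusted p = 0.0669 each), aromatic (adjusted p = 0.0754) and small (adjusted p = 0.0930). Members called, adjusted over the list alone, were as many as over all species in every list.

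Stop fractions were higher after oxidation then deacylation at 111 sites and lower at 13, by at least 5 points. Base 33 of tRNA-Asn(GUU) stood at 81.5% ± 16.6 against 34.5% ± 15.8 (SD, n = 3 each), base 45 of tRNA-Arg(ACG) at 60.7% ± 8 against 18.6% ± 6.98 and base 4 of tRNA-Val(UAC) at 32.8% ± 4.90 against 1.98% ± 0.567. Base 39 of tRNA-Thr(GGU) stood at 30.0% ± 1.32 against 0.188% ± 0.0663, base 4 of tRNA-Lys(UUU) at 31.1% ± 3.11 against 3.32% ± 1.4 and base 1 of tRNA-Sec(UCA) at 27.3% ± 6.66 against 1.94% ± 2.02. In tRNA-Leu(CAG) base 13 stood at 34% ± 14.9 against 4.42% ± 3.97 and base 1 at 21.4% ± 10.4 against 0.556% ± 0.962. Depth was low there, with a mean over the 6 libraries of 465 at base 13 and 243 at base 1. It was 160 at base 1 of tRNA-Sec(UCA). Lower sites included base 33 of tRNA-Glu(UUC) at 6.27% ± 2.28 against 37.8% ± 19.7 and base 36 at 63.8% ± 13 against 84.5% ± 2.74. They included bases 32, 36 and 31 of tRNA-Lys(UUU), base 32 at 7.46% ± 1.14 against 37.3% ± 21.8, bases 29 and 34 of tRNA-Gln(UUG), base 34 at 76.7% ± 1.96 against 92.0% ± 2.95. They also included base 31 of tRNA-Pro(CGG) at 1.13% ± 1.79 against 11.1% ± 19.2, where the deacylated then oxidized libraries had a mean depth of 3 reads and the difference of -9.98 points turned to 1.13 points without replicate 1 of that group.

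At any size, limma called 820 sites higher and 352 lower of 2945 between the 2 orders of treatment, of which 287 had 0 stops in all 6 libraries and 494 a mean under 10 stopped reads. With a mean of at least 10 stopped reads 674 were higher and 27 lower of 1683, and limma on the untransformed fraction called 591. Leaving out 1 library ended the call of tRNA-Asn(GUU) base 33 (4 of 6 libraries, highest adjusted p = 0.0837 without oxidized then deacylated replicate 3), of tRNA-Glu(UUC) base 33 (2 of 6, 0.0522 without replicate 1 of that group) and base 36 (5 of 6, 0.118 without deacylated then oxidized replicate 1), of tRNA-Lys(UUU) base 32 (3 of 6, 0.0788) and base 36 (3 of 6, 0.0587), of tRNA-Gln(UUG) base 29 (4 of 6, 0.0631) and of tRNA-Pro(CGG) base 31 (1 of 5, 0.0609). For the last 4 sites the value is without oxidized then deacylated replicate 1, except replicate 3 for tRNA-Lys(UUU) base 36. The change at base 36 of tRNA-Glu(UUC) went from -20.7 to -13.2 points without oxidized then deacylated replicate 2 and at base 32 of tRNA-Lys(UUU) from -29.9 to -18.0 points without deacylated then oxidized replicate 2. Of the 111 higher sites of at least 5 points 12 had a mean depth under 100 in a group.

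Of the modification lists, m2A37 was called between the 2 orders, with 2 of 6 members higher (3 higher and 1 lower adjusted over the list alone) and a median loss of 6.62% against 2.62% (adjusted p = 0.0210; adjusted p = 0.507 with an estimated correlation). U8 was called with 6 of 29 species higher (8 adjusted over the list alone), 7.64% against 3.37% in the median (adjusted p = 0.0391; adjusted p = 0.507 with an estimated correlation), with tRNA-iniMet(CAU) at 12.6% ± 2.89 against 2.49% ± 0.264 and tRNA-Lys(UUU) at 17.2% ± 2.94 against 5.77% ± 1.43. The mnm5s2U34 list, with 2 of 3 members lower, had an adjusted p of 0.0541, and the other 7 lists had values between 0.323 and 0.826, with signs that differed between test, median and mean for t6A37, unmodified A37 and cmo5U34. With the replicate number as a block 0 lists were called (adjusted p = 0.109 for m2A37 and 0.0728 for U8). The count of 2 also went to 0 without oxidized then deacylated replicate 1 or 3 or without deacylated then oxidized replicate 1 or 2, and it was 3 without deacylated then oxidized replicate 3. Camera at the preset correlation called U8 up (adjusted p = 0.000281) but not m2A37 (adjusted p = 0.192). It called mnm5s2U34 and ms2i6A37 down (adjusted p = 0.00639 and 0.0101). Over all bases, 1223 of 2887 3-base windows were called higher and 235 lower, and fry does not compare a list with them.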

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

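Single genes, added copies, the minimum of 10 stopped reads, the pairing of tRNA shares, the stretches counted as tRNA and the joint removal of untreated replicate 1 and DNase replicate 3 were chosen after seeing the data, and the other settings before. No named species or site reversed in its test, which for sites is on the logit scale, but the difference in percent at base 31 of tRNA-Pro(CGG) turned from -9.98 to 1.13 points without deacylated then oxidized replicate 1. Named species kept their call or lack of it in 478 values, gained a call in 3 and lost it in 6, and on leaving out 1 library in 393, 3 and 18. Named sites kept it in 263 and lost it in 46, and on leaving out 1 library in 211 and 66. Of 47 named sites 33 lost a call somewhere, 29 of them with the untransformed fraction. Summing by anticodon coincided with the species used and was not run. Where a value changed, the cause was not tested. Depth limits the sites, of which 198, 522 and 494 of the calls in the last 3 comparisons had a mean under 10 stopped reads.

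For DNase against untreated, species called went from 2 to 4 with DESeq2, 4 with all 15 libraries, 6 with single genes and 6 without untreated replicate 1 and DNase replicate 3 together. Sites went from 0 to 49 with all 15 libraries and 71 without those 2 libraries. Amino acid lists went from 5 to 1 with camera at the preset correlation, 0 at an estimated one and 0 without TMM. For deacylated against DNase, sites went from 1 to 0 with all 15 libraries, 0 with at least 10 stopped reads and 0 with 3-base windows. Camera at the preset correlation called 3 modification lists and 1 amino acid list in place of 0.

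For oxidized then deacylated against deacylated, single genes gave 37 calls, the untransformed fraction 563 sites and 3-base windows 1367. Modification lists went from 4 to 2 with camera at the preset correlation, 0 at an estimated one and 2 with the single step, and amino acid lists from 8 to 0 with camera at either correlation. For deacylated then oxidized against deacylated, single genes gave 65 calls, the untransformed fraction 26 sites and at least 10 stopped reads 132. Modification lists went from 0 to 3 with camera at the preset correlation and 3 with the single step, and amino acid lists from 13 to 1 with camera at the preset correlation and 0 at an estimated one. For oxidized then deacylated against deacylated then oxidized, single genes gave 68 calls, the untransformed fraction 591 sites and at least 10 stopped reads 701. Modification lists went from 2 to 0 with camera at an estimated correlation and 0 with the single step, and amino acid lists from 12 to 1 with camera at the preset correlation and 0 at an estimated one.

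With the replicate number as a block, DNase against untreated had 0 species and 0 amino acid lists, and deacylated against DNase had 2 species and 0 sites. Replicates were not taken to pair there (correlations -0.30, 0.05 and -0.17, and -0.17, 0.24 and -0.11) nor in deacylated then oxidized against deacylated (0.44, 0.49 and 0.04). In the last of these, replicates 1 and 2 correlated best with their own number and replicate 3 did not. The block changed no count there by over 1.5 times. In DNase against untreated the block left tRNA-Ile(CAU) at 1.47 (adjusted p = 0.131) and tRNA-Ile(GAU) at 1.04 (adjusted p = 0.0803). In deacylated then oxidized against deacylated it ended the calls of base 34 of tRNA-Cys(GCA) (adjusted p = 0.0624), base 46 of tRNA-Lys(UUU) (adjusted p = 0.0795) and the class I list (adjusted p = 0.05003). Where numbers were taken to pair, the block gave 5 amino acid lists and 3 modification lists up with 1 down in oxidized then deacylated against deacylated, and 8 amino acid lists and 0 modification lists between the 2 oxidized groups. There it changed no call of a named species or site, of any other list, and no other count by over 1.5 times. Paired by number, the tRNA share differed by 1.18 points for oxidized then deacylated against deacylated and 0.0665 points between the oxidized groups (exact p = 0.25 each by sign flips of the block, the smallest of 3 pairs). Unpaired numbers gave 0.516 (exact p = 0.5), 0.145 (exact p = 1) and 1.114 points (exact p = 0.25) for the other 3 in order. No paired analysis was possible for the stop landscape or replicate agreement because the former describes 1 group and the latter compares libraries within groups.

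The stop landscape difference for t6A37 was 3.01 points with the single step. The tRNA share differences by reads were 0.428 points for oxidized then deacylated and 0.333 points for deacylated then oxidized against deacylated. With the depth of the unannotated stretches counted as tRNA they were 0.769, -0.0657, 0.742, 0.582 and 0.159 points in the order of the comparisons (exact p = 0.4, 0.8, 0.1, 0.1 and 0.1). Replicate agreement by Spearman correlation was lowest at 0.747 for stops in untreated, 0.933 for counts and 0.830 for stops in DNase, 0.961 and 0.845 in deacylated, 0.982 and 0.850 in oxidized then deacylated, and 0.986 and 0.788 in deacylated then oxidized libraries.

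Leave-one-out ranges were 0 to 6 species, 0 to 5 sites, 0 to 2 modification lists and 0 to 3 amino acid lists for DNase against untreated, and 0, 0 to 4, 0 to 1 and 0 for deacylated against DNase. They were 16 to 24, 638 to 770, 1 to 4 and 2 to 9 for oxidized then deacylated against deacylated, 33 to 35, 477 to 581, 0 to 1 and 12 to 14 for deacylated then oxidized against deacylated, and 33 to 37, 893 to 1065, 0 to 3 and 9 to 11 between the 2 oxidized groups. Stop landscape differences ranged from 92.1 to 94.1 points for ms2i6A37, 25.6 to 34.2 for t6A37, 84.9 to 88.0 for m1G37 and -1.08 to -0.659 for m2A37. The tRNA share differences ranged from -0.0132 to 0.945, -0.118 to 0.295, 1.03 to 1.44, 0.963 to 1.38 and 0.0382 to 0.0863 points in the order of the comparisons.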

Other observations

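All tests of explanations and all regroupings of libraries in this part were chosen after the results were seen.

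Reads covering the first base past the mature 3' end were seen at aspT and valV. Another tRNA gene follows closely on the same strand, with aspT ending at 3946948 and trpT starting at 3946957, and valV ending at 1746511 and valW starting at 1746516. Such reads may start in the next tRNA or in the spacer, as in unprocessed precursors, and their source was not tested. They also enter the 3'-end counts of aspT and valV. At aspT they made up 17.6% ± 2.94 of reads in deacylated libraries and 21.2% ± 6.92 in untreated ones, against 0.105% ± 0.0432 after oxidation then deacylation and 1.25% ± 0.112 after deacylation then oxidation (SD, n = 3). At valV the values were 6.18% ± 0.116, 15.5% ± 3.54, 0.0930% ± 0.00993 and 0.184% ± 0.0111. These differences were not tested, and the 2 genes were chosen after their values were seen.

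The tRNA make-up after deacylation then oxidation, with isoleucine and valine tRNAs high and proline and asparagine tRNAs low, was weighed against 3 explanations. Whether a single abundant species was the cause was not settled. Without tRNA-Ile(GAU), 32.8% of the reads, 93.9% of the other called species (31 of 33) kept call and direction. TMM trims extreme species in both fits, so this refit could change little. Without TMM, the full set gave 10 rises and 25 falls in place of 13 and 21. Amino acids that stayed on through deacylation may account for it, since 95.7% of the variance of log2 folds lay between amino acids (32 species, 11 amino acids; permutation p = 1e-05, the smallest possible here; 95th percentile of shuffled species 52.4%), but other properties shared by tRNAs of an amino acid would give the same result and stay open. Incomplete oxidation of free 3' ends stays open too. The depth of ffs, which carries no amino acid, fell at least 8.84-fold in each of the 9 pairs of libraries but was 37.6 against 2.54 reads per 1000000 tRNA reads in the other order, and the ribosomal RNA share was 0.0823% against 0.0713% in deacylated RNA (exact p = 0.7). In maximum depth, the ribosomal RNA genes rrlG and rrlD fell, from 68.7 to 13.5 and from 67.8 to 11.9 reads per 1000000 tRNA reads. Values per tRNA read also depend on how much tRNA each treatment left ligatable. They therefore do not give the amount of an RNA that escaped oxidation.

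The low 4 serine tRNAs and tRNA-Thr(UGU) after oxidation then deacylation were weighed against 2 explanations, while tRNA-Thr(GGU) and tRNA-Thr(CGU) were not called by edgeR (adjusted p = 0.0879 and 0.148) and were by DESeq2 (adjusted p = 0.0309 and 0.0305). Low charging of these tRNAs could not be told from the data, with a median log2 fold of deacylated over DNase of -0.28 for the 5 species. Oxidation of the bound serine or threonine, which would remove their shield, could not be told either. Threonine tRNAs lay below isoleucine and valine tRNAs by -1.10 in mean log2 fold after deacylation then oxidation (exact p = 0.0286, the smallest of 35 splits of species), but this value shares its deacylated libraries with the fall itself, and isoleucine and valine tRNAs were among the highest there.

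The rise of stop fractions after oxidation then deacylation was weighed against 3 technical explanations. Rises were not confined to shallow positions, at 30.6% of positions of at least 1000 reads against 27.1% of all positions. Low depth was not settled by this. Since 2549 of the 3009 positions were in both sets, the share could not have fallen low enough to point to depth. Deeper positions are also more easily called. Few stopped reads were less likely, with rises at 31.7% of positions with a mean of at least 10 stopped reads in the deacylated libraries (517 of 1631). A rise at every position alike stays open, since the U8 windows, at percentile 97.7 of 10000 draws of random windows, were tested because that list had the lowest fry adjusted p (0.00256). Oxidation of 4-thiouridine or of other modified bases was not tested and stays open.

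Depth between ompT and envY (586060 to 586101, ASM584v2) followed tRNA-Arg(UCU) with a ratio between 0.982 and 1.04 and a coefficient of variation of 1.58% over the 15 libraries, which is consistent with reads of that tRNA placed on a copy of its 3' end. A stretch between intF and yagP (297215 to 297254) followed tRNA-Thr(CGU) less closely, at r = 0.897. In reads per 1000000 without TMM, the log2 fold of ssrA between the 2 oxidized groups, 3.56, differed by -0.39 from the mean of the alanine tRNAs (4.20 and 3.69). These alanine values are unscaled and so larger than the TMM-scaled folds given above. Alanine on the tmRNA was not settled by this, because rnpB, whose RNA carries no amino acid, was 5.42-fold higher in the same direction (11.7 against 2.16 reads per 1000000 tRNA reads), as were rutA (3.16-fold) and sfmD (2.77-fold). Most of the 21 non-tRNA genes compared went the other way (14 lower after oxidation then deacylation), with ratios of 0.0676 for ffs, 0.0635 for chiZ and 0.0991 for ssrS. All these values are per tRNA read and also depend on how much tRNA each order left ligatable. Not all of these genes are separate RNAs. The genes insA6 and yrhA overlap and had identical values, and the peak of chiP lay beside chiZ. The depths of rutA and sfmD were close to each other in every library, as were those of rrlG and rrlD and of ychS and rttR. Whether the members of these pairs are separate RNAs was not tested.

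Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. For DNase against untreated, 1 split, the real one, gave as many as 2 species and 5 amino acid lists (highest other 0 each), and all 10 gave as many as 0 sites (highest other 1) and 0 modification lists (highest other 0). For deacylated against DNase, all 10 gave as many as 0 species and 0 modification lists (highest other 0) and 0 amino acid lists (highest other 1), and 1 gave as many as 1 site (highest other 0). For deacylated then oxidized against deacylated, 1 gave as many as 34 species, 695 sites and 13 amino acid lists, and 10 gave as many as 0 modification lists (highest other 0 each). For the 2 comparisons whose numbers were taken to pair, 1 split gave as many calls as the real one, with 20 and 35 species, 858 and 1172 sites, 4 and 2 modification lists and 8 and 12 amino acid lists, and the 4 splits that part all 3 pairs, the real one among them, gave 0 otherwise.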
